A study of Mus musculus with 9 samples.

How the data were processed

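Expression was measured on 9 one-colour Affymetrix mouse arrays, 1 per RNA sample, in 3 groups of 3. Per the labels' protocols, biotinylated cRNA was made from 100 ng of total RNA of freshly harvested bone marrow. The deposited table holds 1 intensity per probe set and array for 45101 probe sets. Per the submitters' processing notes the authors made these intensities with RMA, which corrects background, makes the arrays' distributions alike by quantile normalization and summarises the probes of a set by median polish. The version, the software and the chip definition are not given in the sources used here. RMA usually returns log2 values, but these range from 4.60 to 32082 with medians of 146 to 156 per array, so they are on a linear scale, and log2(value + 1) was taken. Log2 differences are therefore on the log2(value + 1) scale, which slightly understates changes of dim probe sets. No value is missing. The same value stands on at least 2 arrays for 32.4% of probe sets, and 3.61% have 6 or fewer different values over the 9 arrays, so the spread of some probe sets within a group is understated or 0 before moderation.

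Quantile normalization assumes that the arrays share 1 distribution, so a change of most genes in 1 direction would be removed by it. The array has no sequencing depth, and the number of arrays limits the precision. Dim probe sets have a floor set by background: the 9 probe sets of the Y-linked genes Kdm5d, Eif2s3y and Uty lay between 2.97 and 4.71 (log2) on all 9 arrays, while Xist was high on all of them, so these low values gauge background, and differences among values near 4 carry little information. Probe sets whose names end in _s_at or _x_at can bind transcripts of several related genes.

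Gene names came from the platform annotation supplied with the values. It gave 1 gene symbol for 34958 probe sets and several for 932, and 9211 were not listed. Symbols were looked up by gene ID in an NCBI RefSeq gene table of assembly GRCm38.p6, where 34754 probe sets matched and 204 did not, and no symbol changed. That table also gave each gene's chromosome and neighbours. No genome build is named for the deposited values, so no coordinates are given. Each of 18194 genes was represented by its probe set with the highest mean over all 9 arrays, chosen without regard to group, and 9012 genes had more than 1 probe set. Probe sets with no symbol or several were left out of the gene tests. The 64 control probe sets were not removed as such, so those annotated with 1 gene symbol could enter.

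Groups came from the labels. The replicate numbers 4, 5 and 6 of the MLL-AF9 groups are those of the labels, and the Hoxa9-Meis1 arrays were numbered 1 to 3 in accession order. The design text and labels do not say that each array stands for a separate mouse or a separate primary leukemia, so p-values measure the spread between these samples, which may in part be technical. No pair of arrays was a duplicate: the smallest mean absolute difference between a pair was 0.22 (log2).

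All 9 arrays were fitted in 1 group-means model with limma 3.58.1 (lmFit and eBayes, default settings) in R 4.3.3, with two-sided tests and Benjamini-Hochberg adjustment over all genes of a comparison. A gene was called at a limma adjusted p under 0.05. The comparisons were Af10 deleted versus floxed, floxed versus Hoxa9-Meis1 and deleted versus Hoxa9-Meis1. Both MLL-AF9 groups were sorted for tdTomato and came from secondary recipients, whereas the Hoxa9-Meis1 cells were primary leukemias used without sorting or other treatment, so oncogene, transplant generation, vector and sorting cannot be told apart in the latter 2 comparisons. In the deleted versus floxed comparison, loss of Af10 cannot be told apart from expression of Cre itself, which only the deleted group carried. No scan date, slide or other batch was given.

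Before the data were examined, 24 gene lists were fixed for testing: the HoxA cluster, other Hox clusters, MLL fusion targets outside HoxA, the DOT1L complex and elongation partners, stem and progenitor genes, primary granule genes, late neutrophil genes, monocyte and macrophage genes, antigen presentation by MHC class II, cell cycle genes, Myc targets and ribosome biogenesis, p53 targets, apoptosis and survival genes, interferon response genes, immediate early and cell handling genes, hypoxia and glycolysis genes, cholesterol synthesis genes, unfolded protein response genes, and markers of erythroid cells, of megakaryocytes and platelets, of mast cells, basophils and eosinophils, of B cells, of T and NK cells, and of stromal and endothelial cells. Some genes stand in several lists, such as Meis1, Flt3, Bcl2, Kit, Egr1, Atf3 and Btg2. The lists came from general knowledge of these leukemias and not from these arrays. Each list was tested with limma's camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 24 lists of a comparison. Camera with an estimated correlation and fry were alternatives. Members were counted as risen or fallen only if called over all genes, and the count adjusted over the list alone is given beside it where it differs.

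The genes named were also fixed by a rule before the data were examined. In each comparison these were Mllt10, Mllt3, Hoxa9 and Meis1, the 10 largest rises and 10 largest falls among called genes whose groups did not overlap, up to 4 members with the smallest p of each list past its test and up to 2 of each other list. All HoxA genes could be named. A few further genes are named as chosen after their values were seen.

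The steps were tested on simulated data made from the real means and spreads of the 18194 genes, with 200 genes changed. For deleted versus floxed, 14% of genes changed by 0.5 on the log2 scale were recovered, 68% at 1, 98% at 2 and 100% at 3, with 6 false calls among 146, and 0 of the 24 unchanged lists were called. Changes under about 1 are therefore often missed with 3 arrays per group. The simulated genes were drawn independently of each other, whereas list members can correlate (estimated correlation 0.493 for late neutrophil genes). The 0 lists called thus do not test camera on correlated lists.

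The alternatives were the 2 groups compared alone, eBayes with trend and robust settings, leaving out the dimmer genes, every probe set, the mean of a gene's probe sets, centring each array on its median, another quantile normalization, array weights, an added threshold of 1 on the log2 change, the replicate number as a block, and leaving out each array in turn. A pseudocount of 32, leaving out deleted replicate 6 with floxed replicate 5, and leaving out genes on chromosomes 1, 5 and 15 were added after the data were seen.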

Results

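The arrays compared mouse leukemias driven by the MLL-AF9 fusion with and without Af10, a partner of the histone methyltransferase DOT1L encoded by Mllt10. Primary MLL-AF9 leukemias carrying 2 floxed copies of the gene had been transduced with a tdTomato vector, either empty or expressing Cre recombinase, and transplanted into secondary recipients. There were 3 arrays of Af10 deleted leukemias (Cre), 3 of Af10 floxed leukemias (empty vector) and 3 of primary leukemias made by transduction of Hoxa9 and Meis1, used as the comparison leukemia. The median intensity per array was between 146 and 156. Arrays correlated at 0.980 to 0.990 within groups and at 0.941 to 0.972 between groups (Pearson's r of log2 values across probe sets, which are not independent). Errors after ± are SD over the 3 arrays of a group, and SE is that of the fitted difference.

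Single arrays stood apart in some respects. Floxed replicate 5 had the largest gap between the 3' and 5' control probe sets of Gapdh, a measure of RNA integrity, at 1.03 (log2), against 0.44 to 0.62 on the other MLL-AF9 arrays and 0.67 to 0.81 in Hoxa9-Meis1 leukemias. The same gap for beta-actin did not set that array apart: it was -0.37 there, within the range of all arrays, -0.41 to -0.34. Genes on chromosome 1 were higher by a median of 0.32 in deleted replicate 6, genes on chromosome 15 by 0.26 in floxed replicate 4, and genes on chromosome 5 by 0.15 in floxed replicate 6. In floxed replicate 5 many chromosomes departed from the array's centre, from -0.17 for chromosome 7 to 0.20 for chromosome 13, and the SD of its chromosome medians (0.102) was the highest of the 9 arrays.

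The targeted gene was lower in the deleted leukemias. All 4 Mllt10 probe sets fell, by 0.76 to 1.05 on the log2 scale, and their limma adjusted p lay between 0.000965 and 0.0307 in the fit over all probe sets. The probe set that represented the gene was at 10.95 ± 0.40 in floxed leukemias and fell by 0.95 on the log2 scale (SE 0.21, 1.93-fold, limma adjusted p = 0.0293). The labels do not say which part of the gene is floxed, so a probe set may lie outside the deleted part, and the transcript was lowered and not lost at these probe sets. When deleted replicate 4 or 5 or floxed replicate 4 or 6 was left out, 2 of the 4 probe sets were past the threshold. The representative one was not among them (limma adjusted p = 0.09, 0.0876, 0.0757 and 0.0736). Nor did it pass with only the 2 groups compared in the fit (0.0591) or with the replicate number as a block (0.0603). Mllt3, the gene of the fusion partner AF9, was at 7.94 ± 0.07 in deleted and 7.98 in floxed leukemias and did not pass (limma adjusted p = 0.937). That probe set had the same value on every floxed array (SD 0). The group means of its other probe sets were 4.63 to 4.81, in or near the range of the Y-linked probe sets. These values therefore say little about a change of Mllt3.

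Comparison of deleted with floxed leukemias asks which transcripts differ after Cre deletion of Af10 in established MLL-AF9 leukemia. The HoxA cluster, transcription factor genes that MLL fusions keep active, was lower after deletion: 7 of 9 measured members fell (8 adjusted over the list alone) and 0 rose, with a median difference of -2.26. Hoxa5 fell from 9.79 ± 0.17 to 6.74 ± 0.18 (8.31-fold, SE 0.14 log2, limma adjusted p = 1.59e-05), Hoxa7 from 10.26 ± 0.58 to 8.33 ± 0.28 (3.81-fold, limma adjusted p = 0.0043), and Hoxa2 and Hoxa4 fell 4.78-fold and 4.59-fold. Hoxa9 fell from 12.16 ± 0.39 to 9.15 ± 1.57 (8.07-fold, difference -3.01, SE 0.63, limma adjusted p = 0.0242) and Hoxa10 from 10.90 ± 0.26 to 7.83 ± 1.67 (8.38-fold, limma adjusted p = 0.0271). Their wide spread came from deleted replicate 6, where Hoxa9 was at 7.35, against 9.90 and 10.20 in the other deleted leukemias, and without that array the differences were -2.11 for Hoxa9 and -2.10 for Hoxa10. Hoxa11 fell by 0.80. Hoxa3 was at 9.37 ± 1.62 in deleted and 11.88 ± 0.23 in floxed leukemias by the probe set that represented it (limma adjusted p = 0.0529, and 0.000292 without deleted replicate 6), while its other 3 probe sets fell, by 0.82 to 4.28, and Hoxa13 was dim and did not pass. The list was past the camera test (adjusted p = 6.22e-10) and also with an estimated correlation (adjusted p = 0.0163). Leaving out floxed replicate 4, 5 or 6 raised the limma adjusted p of Hoxa9 to 0.0631, 0.0638 and 0.0538, and that of Hoxa10 to 0.0587, 0.102 and 0.05. With only the 2 groups compared in the fit it was 0.0686 for Hoxa9 and 0.0726 for Hoxa10, and with the replicate number as a block 0.0737 and 0.0599. Hoxa2 in deleted leukemias (4.11) lay within the range of Y-linked probe sets, 2.97 to 4.71, taken as background, so its fold is a lower bound. The other probe set of Hoxa10 differed by -0.29 and did not pass. It lay within that range in deleted (3.46) and floxed leukemias (3.76), so it says little about Hoxa10.

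**Figure D1:**
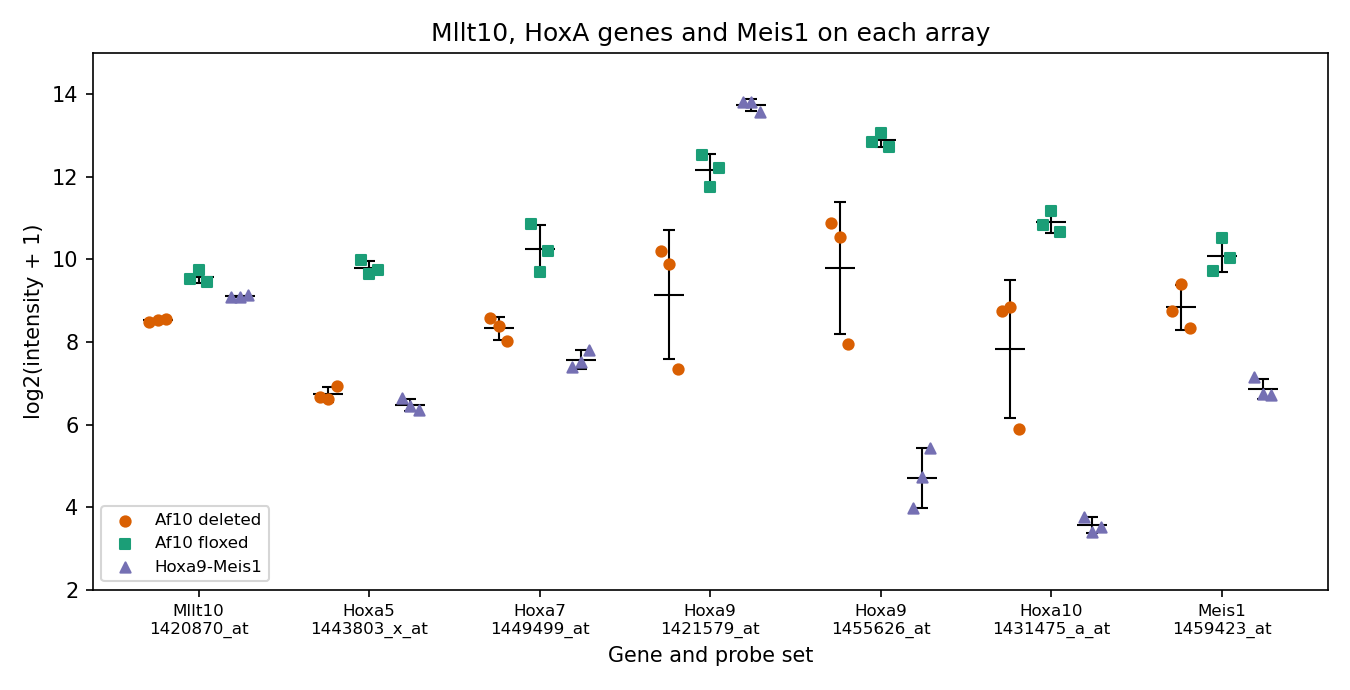
Expression of Mllt10, Hoxa5, Hoxa7, Hoxa10, Hoxa9 by both of its probe sets and Meis1, as log2(intensity + 1) on the y axis, with the gene and probe set on the x axis. Each point is 1 array, and the bars give the mean and SD of the 3 arrays of a group. Hoxa5 lay at 9.79 in floxed, 6.74 in deleted and 6.48 in Hoxa9-Meis1 leukemias, and the Hoxa9 probe sets stood at 13.74 and 4.71 in Hoxa9-Meis1 leukemias.

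Further genes known as targets of MLL fusions were lower too. Of 21 measured MLL fusion targets outside HoxA, 8 fell (13 adjusted over the list alone) and 1 rose, with a median of -0.88 (camera adjusted p = 3.44e-07; adjusted p = 0.0163 with an estimated correlation). Flt3, a receptor tyrosine kinase of progenitors, fell from 11.76 ± 0.40 to 7.19 ± 0.33 (23.6-fold, limma adjusted p = 3.43e-05). Mef2c, a transcription factor gene, fell 16.0-fold (difference -4.00, SE 0.30, limma adjusted p = 0.000154), and the survival gene Bcl2 fell 4.84-fold (limma adjusted p = 0.000401). Meis1, whose product binds DNA with Hoxa9, fell 2.39-fold, from 10.09 ± 0.40 to 8.84 ± 0.54 (limma adjusted p = 0.0344), and 1 of its 3 probe sets passed, all being lower. Leaving out deleted replicate 4 or 6 or floxed replicate 5 or 6 ended that call, with limma adjusted p of 0.103, 0.0893, 0.12 and 0.0653, as did a fit of only the 2 groups compared (0.0762) and the fit without deleted replicate 6 and floxed replicate 5 together (0.196). Eya1, another gene of this list, rose 10.8-fold, from 5.72 ± 0.09 to 9.16 ± 0.13 (limma adjusted p = 6.14e-06).

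Lists of blood cell identity changed as well, with calls that depended on the test. Of 22 stem and progenitor genes, 5 fell (6 adjusted over the list alone, with 1 rise): Cd34 fell 11.8-fold (limma adjusted p = 0.00308), Mycn 2.07-fold, Bmi1 2.08-fold, Kit 1.95-fold, and Meis1 as above. For Mycn only 1 of 3 probe sets was lower, and the mean of its probe sets did not pass (difference -0.27, limma adjusted p = 0.135), nor did that of Kit (-0.82, limma adjusted p = 0.0747). Bmi1 and Kit passed by 1 of 2 probe sets each. The camera adjusted p was 0.031 (adjusted p = 0.762 with an estimated correlation), and it was 0.0841 without deleted replicate 5, 0.114 without floxed replicate 6, 0.0554 without deleted replicate 6 and floxed replicate 5 together, and 0.196 without genes on chromosomes 1, 5 and 15. The test fry, which does not compare a list with other genes, gave 0.138. The list median, -0.11 with all arrays, turned to 0.01 without floxed replicate 6, so the direction of this list is not settled. Without the 3 chromosomes it was 0.10. That setting drops any list members that lie on them, here and for the other lists, so it does not test the same genes. Of 21 late neutrophil genes, 3 rose (4 adjusted over the list alone): Lrg1 4.53-fold, the chemokine receptor gene Cxcr2 3.72-fold and Wfdc21 3.21-fold. That list had a camera adjusted p of 0.031 (adjusted p = 0.802 with an estimated correlation), of 0.0527 with only the 2 groups compared in the fit, of 0.0652 without the 3 chromosomes, of 0.276 by fry, and of 0.175, 0.118 and 0.197 without deleted replicate 4, deleted replicate 5 and floxed replicate 5. Of 16 genes for antigen presentation by MHC class II, 4 fell, among them H2-Ob (18.5-fold), H2-Oa (3.94-fold) and H2-DMa (2.34-fold), besides Flt3, and Cd80 rose by 1.13 on the log2 scale (camera adjusted p = 0.0205; adjusted p = 0.333 with an estimated correlation). That p was 0.118 without floxed replicate 6, where the list median turned from -0.21 to 0.12, 0.0554 without deleted replicate 6 and floxed replicate 5 together, and 0.0914 without the 3 chromosomes. Of 19 T and NK cell markers, 4 rose (5 adjusted over the list alone) and 1 fell (camera adjusted p = 0.00453; adjusted p = 0.12 with an estimated correlation). Gzma and Klrd1 lay within the background range in floxed leukemias, so their rises are understated: Gzma rose from 4.49 ± 0.32 to 6.06 ± 0.25, Klrd1 from 4.18 ± 0.28 to 5.32 ± 0.30 and Cd3e from 6.84 ± 0.05 to 7.77 ± 0.10, Thy1 rose by 1.07, and Cd5 fell from 6.94 ± 0.09 to 5.74 ± 0.25. Cd80 and Thy1 were named after their values were seen. Leaving out 1 array ended the calls of Bmi1 (deleted replicate 4, 5 or 6 or floxed replicate 4 or 5; limma adjusted p up to 0.0967), Kit (any of the 6; up to 0.112), Wfdc21 (any but floxed replicate 4; up to 0.119), H2-DMa (any floxed array; up to 0.0685) and Klrd1 (floxed replicate 5; 0.0531). Without deleted replicate 6 and floxed replicate 5 together the limma adjusted p was 0.188 for Bmi1, 0.157 for Kit, 0.153 for Wfdc21, 0.0531 for H2-DMa and 0.101 for Klrd1. With only the 2 groups compared in the fit it was 0.0569 for Bmi1, 0.0698 for Wfdc21 and 0.0571 for H2-DMa. Array weights also ended the call of Bmi1 (0.0552), a pseudocount of 32 those of Kit (0.0577) and Wfdc21 (0.0618), and quantile normalization that of Kit (0.0734). The difference of H2-Ob was -4.21, and -4.90 without floxed replicate 4.

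The largest single changes lay outside these lists for the most part. Hpgd, which encodes a prostaglandin-degrading enzyme, fell 189-fold, from 13.06 ± 0.12 to 5.50 ± 1.01 (difference -7.56, SE 0.59, limma adjusted p = 0.000182). Besides Flt3, named above, next in size were the falls of Cnn3, a calponin gene (49.7-fold), the potassium channel gene Kcnq5 (35.0-fold), Hmgn3, a nucleosome-binding protein gene (33.7-fold), desmoplakin (Dsp, 30.0-fold), Ly6k (28.7-fold), the chromatin organiser gene Satb1 (24.6-fold), the nuclear receptor gene Hnf4a (21.3-fold) and Npas3 (19.2-fold). Among the rises, Mab21l1 went from 4.55 ± 0.10 to 10.17 ± 1.70 (49.3-fold, limma adjusted p = 0.00162). The transcription factor gene Pou4f1 went from 7.43 ± 0.03 to 12.03 ± 0.31 (24.2-fold, limma adjusted p = 1.59e-05), and Sox6 rose 20.5-fold. Cldn23 rose 21.5-fold, Smad1, a mediator of BMP signals, 16.0-fold, the collagen gene Col5a3 16.0-fold, Tfpi, an inhibitor of blood coagulation, 15.3-fold, Tanc1 12.6-fold (by 1 of its 2 probe sets) and the p53 target Perp 12.5-fold. In floxed leukemias Mab21l1, Cldn23 (3.94) and Perp (4.57) lay within the background range, so their folds are lower bounds and their rank by size is uncertain. Ly6k fell by 1 of its 2 probe sets (the other differed by -0.26) and Npas3 by 3 of 4, and without deleted replicate 6 and floxed replicate 5 together Smad1 did not pass (limma adjusted p = 0.0901). The difference of Mab21l1 was 5.62, and 6.60 without deleted replicate 5, and that of Dsp was -4.91, and -4.31 without deleted replicate 4. Ear3 rose 17.4-fold and belongs to a family of closely related ribonuclease genes whose probes can cross-hybridise.

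The remaining 18 lists were not past the camera test, and counts adjusted over the list alone were equal unless given. In limma 0 genes passed among 32 cell cycle genes (list adjusted p = 0.534), 29 Myc targets and ribosome biogenesis genes (0.269), 23 hypoxia and glycolysis genes (0.665) and 17 cholesterol synthesis genes (0.27), where 1, 3, 6 and 4 had an unadjusted p under 0.05. The Myc list was past the test without floxed replicate 6 (adjusted p = 0.0274). Of 27 immediate early and cell handling genes 0 passed and 10 had such a p, at a median of 0.58 and a camera adjusted p of 0.0597. That list was past the test without deleted replicate 6 (adjusted p = 0.00468) or floxed replicate 4 (adjusted p = 0.00124) and without deleted replicate 6 and floxed replicate 5 together (0.0219). The list also passed with the mean of a gene's probe sets (0.041) and with the replicate number as a block (0.00712), and its median expression was lowest on floxed replicate 5. Of 24 genes of other Hox clusters, Hoxb3 rose 2.49-fold and Hoxb13 1.64-fold (list adjusted p = 0.192, and 0.017 by fry); the other probe set of Hoxb3 differed by 0.32 and did not pass. Of 20 genes of the DOT1L complex and elongation partners, Mllt10 and Aff3 (4.81-fold) fell (3 adjusted over the list alone; list adjusted p = 0.228), Aff3 by 1 of its 2 probe sets. Igfbp4 rose 2.14-fold among 13 primary granule genes (3 adjusted over the list alone; list adjusted p = 0.408). Of 27 monocyte and macrophage genes, 3 rose and 3 fell, with F13a1 2.08-fold higher and Ly86 7.63-fold lower (list adjusted p = 0.449). Of 20 p53 targets, Perp and Zmat3 (2.25-fold) rose (3, and 1 fall, adjusted over the list alone; list adjusted p = 0.662). Of 17 apoptosis and survival genes, Bcl2 and Bid (3.86-fold) fell (2, and 1 rise, adjusted over the list alone; list adjusted p = 0.534), Bid by 2 of its 3 probe sets. Mx1 fell 2.2-fold among 23 interferon response genes (list adjusted p = 0.449). Leaving out 1 array ended the calls of Hoxb13 (any but floxed replicate 6; limma adjusted p up to 0.137), Igfbp4 (floxed replicate 5; 0.0524), Mx1 (deleted replicate 4 or 5 or floxed replicate 5 or 6; up to 0.122) and Xbp1 (any deleted array or floxed replicate 4; up to 0.0719). Without deleted replicate 6 and floxed replicate 5 together the limma adjusted p was 0.083 for Hoxb3, 0.216 for Hoxb13, 0.0984 for Igfbp4, 0.0607 for F13a1, 0.118 for Mx1 and 0.11 for Xbp1. With only the 2 groups compared in the fit it was 0.0616 for Hoxb13, 0.062 for Mx1 and 0.0629 for Xbp1. Array weights also ended the call of Hoxb13 (0.0734), and a pseudocount of 32 that of Mx1 (0.0533). Of 20 unfolded protein response genes, 3 rose (3, and 1 fall, adjusted over the list alone; list adjusted p = 0.315): Asns, for asparagine synthetase, 2.98-fold, Xbp1 (limma adjusted p = 0.0245), and Chac1, named after its value was seen, by 1.08 on the log2 scale.

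Markers of other cell types moved singly. Rhd fell 2.15-fold among 21 erythroid markers (list adjusted p = 0.566). Of 16 megakaryocyte and platelet markers, 2 rose and 1 fell, with Cd9 3.21-fold higher and Itgb3 4.12-fold lower by 1 of its 2 probe sets (list adjusted p = 0.409). Kit was the only one called of 17 mast cell, basophil and eosinophil markers (list adjusted p = 0.662). Cd79b fell 1.68-fold and Il7r 5.56-fold among 19 B cell markers (5 rises and 4 falls adjusted over the list alone; list adjusted p = 0.958). Of 19 stromal and endothelial markers, Col5a1 rose 4.03-fold and Pecam1 fell 4.36-fold (2 rises and 1 fall adjusted over the list alone; list adjusted p = 0.662). The list median and the camera direction had opposite signs for the DOT1L complex, monocyte, cell cycle, hypoxia and mast cell lists, and the mean and the direction for the B cell and cell cycle lists. Leaving out 1 array ended the calls of Kit (any; limma adjusted p up to 0.112), Il7r (any deleted array; up to 0.116), Col5a1 (deleted replicate 5 or 6 or floxed replicate 5 or 6; up to 0.129) and Pecam1 (deleted replicate 4 or 5 or floxed replicate 5 or 6; up to 0.0996). The mean of their probe sets did not pass for Il7r (limma adjusted p = 0.0678) and Col5a1 (limma adjusted p = 0.0729), and without floxed replicate 5 the difference of Il7r was -1.65 in place of -2.48. Il7r passed by 1 of 2 probe sets and Col5a1 by 1 of 3. With only the 2 groups compared in the fit the limma adjusted p was 0.0973 for Il7r, 0.0944 for Col5a1 and 0.0515 for Pecam1. A pseudocount of 32 also ended the calls of Il7r (0.0758) and Col5a1 (0.0545), and Col5a1 did not pass with array weights (0.0591) or without deleted replicate 6 and floxed replicate 5 together (0.252).

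In all, 1246 of 18194 genes passed (limma, Benjamini-Hochberg), 585 higher and 661 lower in deleted leukemias, so 47.0% were higher. Centring each array on its median gave 766 higher and 578 lower (57.0% higher), with the median difference of all genes at 0.12 in place of 0.06. The groups did not overlap for 25.9% of genes, against 10% by chance. The count was 736 without deleted replicate 4, 645 without floxed replicate 5, and 498 without deleted replicate 6 and floxed replicate 5 together.

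**Figure D2:**
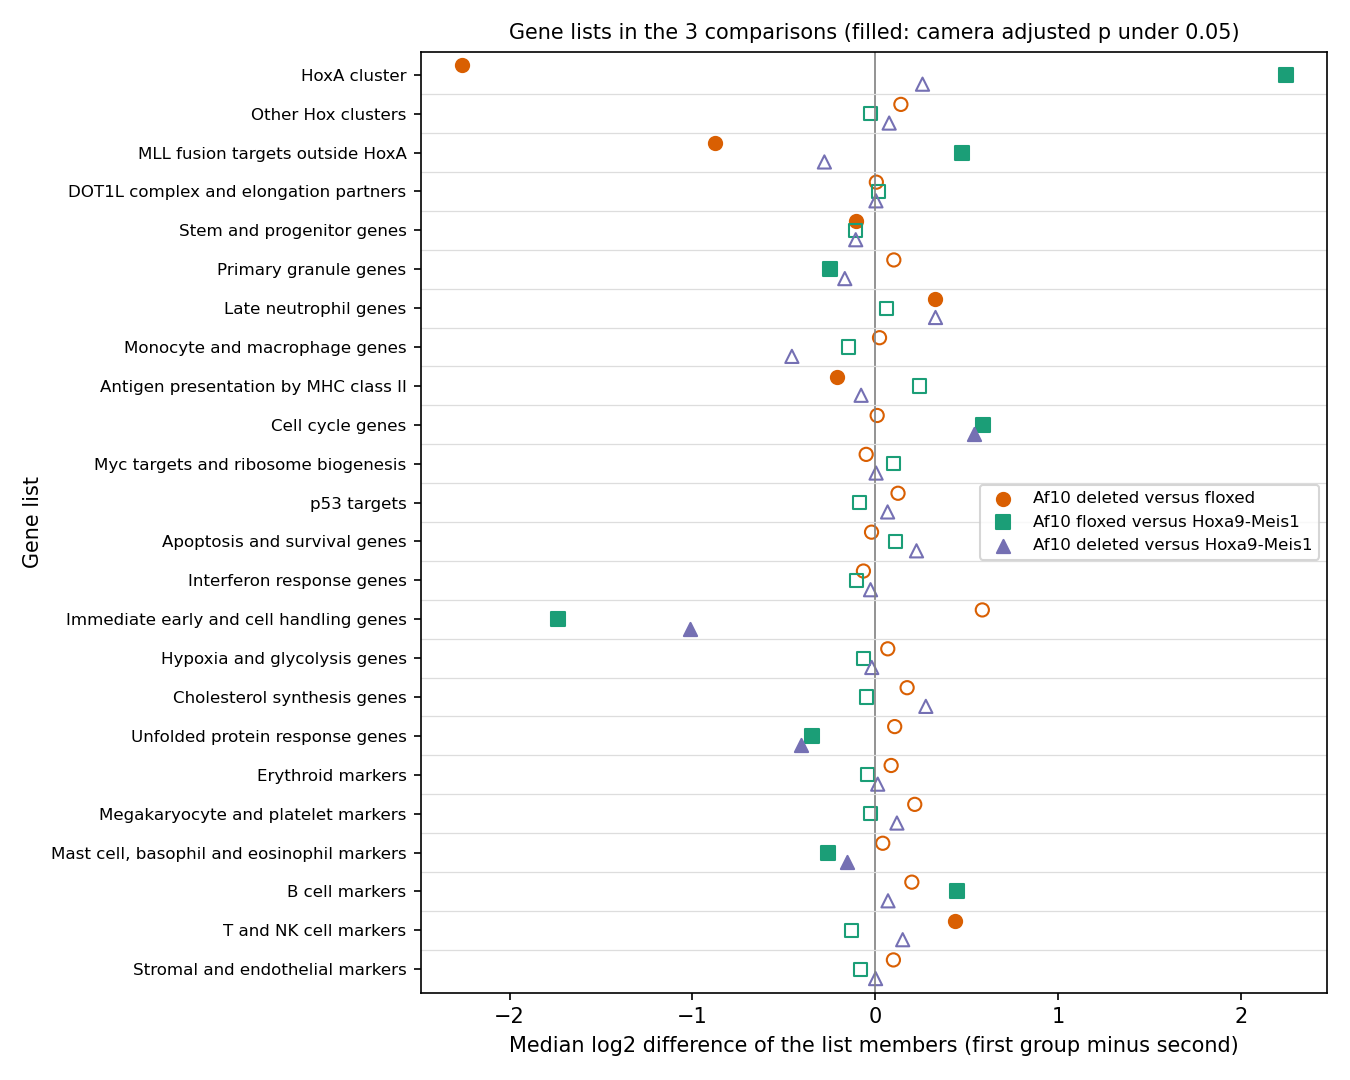
Median log2 difference of the measured members of each of 24 gene lists (x axis, first group minus second) in the 3 comparisons, with the lists on the y axis. Filled symbols mark lists past the camera test at a preset correlation of 0.01. The HoxA cluster lay at -2.26 for deleted versus floxed, 2.25 for floxed versus Hoxa9-Meis1 and 0.26 for deleted versus Hoxa9-Meis1.

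The comparison of floxed with Hoxa9-Meis1 leukemias sets MLL-AF9 leukemia against a leukemia made by 2 of the fusion's target genes. Of 9 measured HoxA genes, the transduced Hoxa9 among them, 7 rose in floxed leukemias (7, and 1 fall, that of Hoxa9, adjusted over the list alone), with a median of 2.25. Hoxa10 was at 10.90 ± 0.26 against 3.56 ± 0.20 (162-fold, limma adjusted p = 0.000362), Hoxa3 was 31.4-fold, Hoxa5 9.93-fold and Hoxa7 6.41-fold higher. In Hoxa9-Meis1 leukemias Hoxa10 lay within the background range, so 162-fold is a lower bound. The other probe set of Hoxa10 differed by 0.54 and did not pass, but it lay within the background range in floxed (3.76) and Hoxa9-Meis1 leukemias (3.22). Hoxa9 depended on the probe set. The one that represented the gene, by its mean over all 9 arrays, was at 12.16 ± 0.39 in floxed and 13.74 ± 0.14 in Hoxa9-Meis1 leukemias (difference -1.58, limma adjusted p = 0.162, and 0.00906 with only the 2 groups compared in the fit and 0.00702 without deleted replicate 6 and floxed replicate 5 together), and the other at 12.88 ± 0.17 and 4.71 ± 0.73 (difference 8.17, limma adjusted p = 0.000262). Meis1 was 9.34-fold higher in floxed leukemias by the probe set that represented it (difference 3.22, SE 0.29, limma adjusted p = 0.000362) and higher by all 3 of its probe sets, although Meis1 had been transduced into the other group. The camera adjusted p of the HoxA list was 1.7e-08 (adjusted p = 0.0562 with an estimated correlation). Of 21 MLL fusion targets outside HoxA, 7 rose (9, and 1 fall, adjusted over the list alone), with Skida1 26.1-fold, Pbx3 5.49-fold and Flt3 4.86-fold higher (camera adjusted p = 0.00136; adjusted p = 0.0763 with an estimated correlation). Skida1 was at 4.54 in Hoxa9-Meis1 leukemias, within the background range, so its fold is a lower bound. Mllt10 and Mllt3 did not pass by their representative probe sets (limma adjusted p = 0.493 and 0.127), although the means of their probe sets did (difference 0.42, limma adjusted p = 0.0462, and -1.11, limma adjusted p = 0.0378). Mllt3 also passed with array weights (0.028) and without Hoxa9-Meis1 replicate 3 (0.00199).

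Immediate early genes, which respond within minutes to stimulation or to cell handling, were lower in floxed leukemias: 16 of 27 fell (22 adjusted over the list alone), with a median of -1.74 (camera adjusted p = 5.56e-14; adjusted p = 0.189 with an estimated correlation). The stress-response gene Atf3 was at 6.38 ± 0.40 against 11.88 ± 0.50 (45.0-fold lower, limma adjusted p = 2.09e-05), Fosb was 16.0-fold, Ier5 4.87-fold and Klf6 4.24-fold lower. The heat shock genes Hspa1a and Hspa1b, near-identical copies that the probes may not tell apart, were 16.0-fold and 17.3-fold lower. Of 20 unfolded protein response genes, 6 fell (9 adjusted over the list alone) and 1 rose (camera adjusted p = 0.000108; adjusted p = 0.189 with an estimated correlation): Atf3, which stands in both lists, Ddit3 (2.80-fold) and the chaperone gene Hspa5 (1.60-fold) fell, and Asns rose 2.22-fold. Cell cycle genes were higher: 15 of 32 rose (24 adjusted over the list alone) and 0 fell, with a median of 0.59 (camera adjusted p = 5.64e-14; adjusted p = 0.0763 with an estimated correlation). Birc5 was 2.19-fold, Aurkb 1.95-fold, Cenpa 1.87-fold and Ccnb2 1.86-fold higher. Cenpa and Hspa5 passed by 2 of 3 probe sets each. The call of Hspa1a ended when floxed replicate 5 or 6 or Hoxa9-Meis1 replicate 1 or 3 was left out (limma adjusted p up to 0.123), and without deleted replicate 6 and floxed replicate 5 together (0.132). The difference of Fosb ran from -4.86 without floxed replicate 4 to -3.40 without floxed replicate 5, and that of Hspa1b from -4.83 to -3.49 without the same arrays (-4.80 without Hoxa9-Meis1 replicate 2). Hspa1a differed by -4.73 without floxed replicate 4 and -4.84 without Hoxa9-Meis1 replicate 2.

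**Figure D3:**
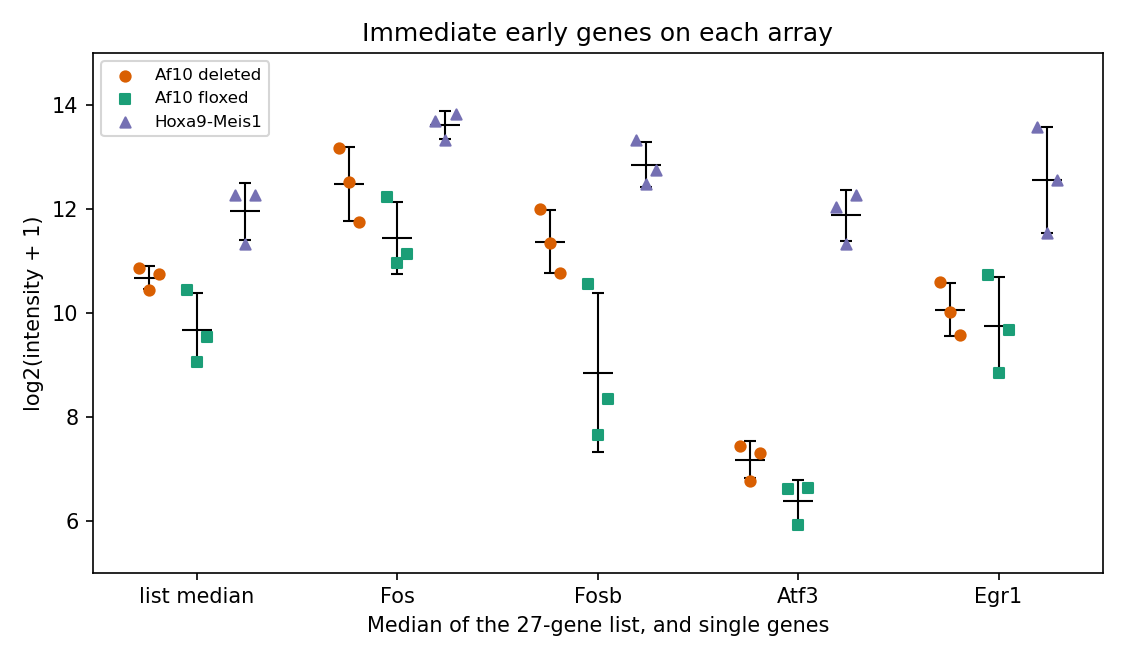
Immediate early genes on each array, as log2(intensity + 1) on the y axis, for the median of the 27-gene list and for 4 single genes on the x axis. Each point is 1 array, and the bars give the mean and SD of the 3 arrays of a group. Atf3 lay at 11.88 ± 0.50 in Hoxa9-Meis1, 6.38 ± 0.40 in floxed and 7.17 ± 0.35 in deleted leukemias.

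Lineage markers differed too between floxed and Hoxa9-Meis1 leukemias. Of 17 mast cell, basophil and eosinophil markers, 4 fell: Cpa3, a carboxypeptidase of mast cells, 19.5-fold (difference -4.28, SE 0.78, limma adjusted p = 0.0119), Ms4a2 7.92-fold, Siglecf 3.67-fold and Fcer1a 3.4-fold (camera adjusted p = 0.0169; adjusted p = 0.607 with an estimated correlation; 0.0926 without Hoxa9-Meis1 replicate 1, 0.0657 without genes on chromosomes 1, 5 and 15, and 0.123 by fry). Of 19 B cell markers, 5 rose, among them Jchain 5.68-fold, Pou2af1 5.24-fold and Bank1 3.50-fold (camera adjusted p = 0.0175; adjusted p = 0.507 with an estimated correlation; 0.0989 without floxed replicate 6, 0.0637 without Hoxa9-Meis1 replicate 3 and 0.11 without the 3 chromosomes). Of 13 primary granule genes, Cebpa fell 2.19-fold (2, and 1 rise, adjusted over the list alone), and that list was lower at a camera adjusted p of 0.0394 (adjusted p = 0.567 with an estimated correlation; 0.189 without floxed replicate 5, 0.103 without Hoxa9-Meis1 replicate 1 and 0.0584 with the mean of a gene's probe sets). For the granule list it was also 0.0648 without the 3 chromosomes, 0.224 without deleted replicate 6 and floxed replicate 5 together, and 0.0914 by fry. Fcer1a in floxed (4.52) and Pou2af1 in Hoxa9-Meis1 leukemias (4.06) lay within the background range, so their folds are lower bounds. The other 16 lists were not past the test, with adjusted p of 0.371 or more, but the monocyte list passed without Hoxa9-Meis1 replicate 2 (0.0268). Leaving out Hoxa9-Meis1 replicate 1 ended the calls of Cpa3 (limma adjusted p = 0.0547), Pou2af1 (0.058), Bank1 (0.0766), Cebpa (0.0755), Ms4a2 (0.12), Siglecf (0.118) and Fcer1a (0.0501). Most of these were also lost without another array: Pou2af1 without floxed replicate 5 (0.0502), Bank1 without floxed replicate 6 (0.0517), Cebpa without floxed replicate 5 (0.0528) or 6 (0.0519), and Ms4a2, Siglecf and Fcer1a without Hoxa9-Meis1 replicate 2 (0.122, 0.112 and 0.0641) or floxed arrays 4 and 6, and the former 2 also without floxed replicate 5 (0.0897 and 0.105). Without deleted replicate 6 and floxed replicate 5 together the limma adjusted p was 0.0549 for Jchain, 0.0549 for Cebpa, 0.114 for Ms4a2 and 0.0528 for Fcer1a. Ms4a2 did not pass with only the 2 groups compared in the fit (0.0844), and a pseudocount of 32 ended the calls of Ms4a2 (0.0545) and Pou2af1 (0.0576). The difference of Cpa3 was -3.55 without floxed replicate 4 and -5.16 without Hoxa9-Meis1 replicate 3, and that of Ms4a2 -2.32 and -3.94 without Hoxa9-Meis1 replicates 1 and 3.

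Besides the genes named above, the largest rises in floxed over Hoxa9-Meis1 leukemias were in Stfa3 (167-fold) and Stfa2l1 (107-fold), stefin genes from a family of near-identical copies, the proenkephalin gene Penk (49.8-fold), Tcf24 (41.1-fold), Col19a1 (30.9-fold), Ly6k (30.2-fold) and Hebp1 (28.4-fold). Besides the genes named above, the largest falls were in Aldh1a7 (37.9-fold), Gdf3 (25.8-fold), Slc15a2 (21.4-fold), Tfpi (16.9-fold) and the uncharacterised transcript 5031426D15Rik (16.0-fold; not called without floxed replicate 5 or 6 or Hoxa9-Meis1 replicate 1 or 2, with limma adjusted p up to 0.096, nor with only the 2 groups compared in the fit, 0.061, nor without deleted replicate 6 and floxed replicate 5 together, 0.0835). Stfa2l1 varied widely in Hoxa9-Meis1 leukemias (6.74 ± 2.43), and it was 68.0-fold, 64.0-fold and 284-fold higher without Hoxa9-Meis1 replicates 1, 2 and 3. The difference of 5031426D15Rik was -3.21 and -5.18 without Hoxa9-Meis1 replicates 2 and 3. Aldh1a7 (4.22) and Slc15a2 (4.67) lay within the background range in floxed leukemias, so their folds are lower bounds and their rank is uncertain. Ly6k rose by 1 of its 2 probe sets (the other differed by 0.25), and Slc15a2 fell by 1 of 3 (another differed by -0.04). In all, 1618 genes passed (limma, Benjamini-Hochberg), 1015 higher and 603 lower in floxed leukemias. The count was 1028 without floxed replicate 5, 681 without Hoxa9-Meis1 replicate 1 and 823 without Hoxa9-Meis1 replicate 2.

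Comparison of deleted with Hoxa9-Meis1 leukemias shows where MLL-AF9 leukemia without Af10 stood against the same reference. The HoxA cluster was not past the list test (camera adjusted p = 0.307), and 2 of 9 members were higher. These were Hoxa10, 19.3-fold by 1 of its 2 probe sets (a lower bound, as above), and Hoxa3, 5.51-fold. The other Hoxa10 probe set differed by 0.24 but lay within the background range in both groups (3.46 and 3.22). Hoxa9 was 24.1-fold lower by the probe set that represented it (difference -4.59, SE 0.63, limma adjusted p = 0.00176) but higher by the other (difference 5.08, limma adjusted p = 0.00159). Hoxa5 differed by 0.26 (SE 0.14, limma adjusted p = 0.271) and Hoxa4 by 0.03. Meis1 was 3.91-fold higher in deleted leukemias by the probe set that represented it (limma adjusted p = 0.00254), and 10.1-fold and 12.7-fold higher by its others. Mllt10 differed by -0.68 (SE 0.21, limma adjusted p = 0.057), and the mean of its probe sets by -0.49 (limma adjusted p = 0.0178). Mllt10 also passed with only the 2 groups compared in the fit (0.0291), without the dimmer genes (0.0403), with array weights (0.0097) and without deleted replicate 6 and floxed replicate 5 together (0.0194). Hoxa3 lost its call without any 1 of the Hoxa9-Meis1 arrays (limma adjusted p up to 0.117), with only the 2 groups compared in the fit (0.0722), with a pseudocount of 32 (0.0586) and with the mean of its probe sets (0.72, limma adjusted p = 0.0636). Its other 3 probe sets differed by -0.07 to 0.35, and the one called was at 11.24 in deleted replicate 6 against 8.30 and 8.57. Without deleted replicate 6 the differences were 1.53 for Hoxa3, 5.23 for Hoxa10 and -3.69 for Hoxa9.

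Cell cycle genes were higher in deleted leukemias, with 20 of 32 called (24 adjusted over the list alone) and a median of 0.54 (camera adjusted p = 9.53e-10; adjusted p = 0.399 with an estimated correlation). Aurka was 2.16-fold (by 1 of its 2 probe sets; the other differed by 0.17) and Cdk1 2.07-fold higher. Immediate early genes were lower: 7 of 27 fell (12 adjusted over the list alone), with a median of -1.01, Atf3 26.1-fold and Tnfaip3 7.08-fold lower (camera adjusted p = 4.8e-09; adjusted p = 0.543 with an estimated correlation). Of 20 unfolded protein response genes, 7 fell (10 adjusted over the list alone) and 2 rose, Asns 6.61-fold and Chac1 2.91-fold (camera adjusted p = 0.00326; adjusted p = 0.543 with an estimated correlation; 0.0736 without genes on chromosomes 1, 5 and 15). Of 17 mast cell, basophil and eosinophil markers, 5 fell (6 adjusted over the list alone), with Cpa3 76.3-fold (difference -6.25, and -7.13 without Hoxa9-Meis1 replicate 3) and Kit 2.31-fold lower (camera adjusted p = 0.0336; adjusted p = 0.659 with an estimated correlation; 0.0555 with only the 2 groups compared in the fit, 0.0532 without deleted replicate 5 and 0.101 without Hoxa9-Meis1 replicate 1). For that list it was also 0.15 without the 3 chromosomes, 0.0733 without deleted replicate 6 and floxed replicate 5 together, and 0.116 by fry. The other 20 lists were not past the test. They included stem and progenitor genes, of which 8 fell and 2 rose (4 rises adjusted over the list alone; camera adjusted p = 0.0605), and late neutrophil genes, of which 5 rose (camera adjusted p = 0.066). The stem list passed without deleted replicate 4 (0.0267) or Hoxa9-Meis1 replicate 3 (0.0019). The neutrophil list passed without deleted replicate 6 (0.0108), without Hoxa9-Meis1 replicate 3 (0.0109) and without deleted replicate 6 and floxed replicate 5 together (0.00371). The monocyte list and the list for MHC class II passed without deleted replicate 4 (0.0262 and 0.0322) or Hoxa9-Meis1 replicate 2 (0.00487 and 0.0356). By fry the other Hox clusters (0.00612), B cell markers (0.0397) and T and NK cell markers (0.00637) passed.

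The largest rises over Hoxa9-Meis1 leukemias were in Tcf24, a bHLH factor gene (306-fold, from 4.81 ± 0.15 to 13.07 ± 0.03), Stfa3 (304-fold), Rnase2a (228-fold), Penk (148-fold), Stfa2l1 (113-fold) and Tanc1 (109-fold), followed by Mab21l1 (47.7-fold), Ces1d (34.3-fold), Col5a3 (32.4-fold) and Slc32a1 (30.4-fold). The largest falls were in Hpgd (92.7-fold), Cpa3, Cnn3 (44.7-fold), the germ-cell helicase gene Ddx4 (41.4-fold), Aldh1a7 (39.9-fold), Hspa1a (35.7-fold), Gem (33.1-fold), Tgm3 (30.8-fold), Hnf4a (29.9-fold) and B3gnt5 (26.8-fold). Tanc1 rose by 1 of its 2 probe sets, and Cnn3 fell by 5 of 6. In 1 of the 2 groups Rnase2a (3.89), Tanc1 (3.99), Mab21l1 (4.59), Ddx4 (3.02) and Aldh1a7 (4.14) lay within the background range, so their folds are lower bounds and their rank is uncertain. Some of these sizes depended on 1 array: Stfa2l1 differed by 6.17, 6.08 and 8.23 without Hoxa9-Meis1 replicates 1, 2 and 3, and Mab21l1 by 6.56 without deleted replicate 5. Hpgd differed by -5.92 and Cpa3 by -7.13 without Hoxa9-Meis1 replicate 3, Gem by -4.45 without replicate 1, and Hspa1a was 61.8-fold, 22.7-fold and 64.2-fold lower without deleted replicate 4, deleted replicate 5 and Hoxa9-Meis1 replicate 2. In all, 2821 genes passed (limma, Benjamini-Hochberg), 1687 higher and 1134 lower (59.8% higher), and centring each array on its median gave 2252 higher and 968 lower (69.9% higher). The count was 1860 without deleted replicate 4, 1540 without Hoxa9-Meis1 replicate 1 and 1636 without Hoxa9-Meis1 replicate 2.

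Of the genes called against Hoxa9-Meis1 leukemias, 957 were called in the same direction in floxed and in deleted leukemias, 602 higher and 355 lower, and 21 in opposite directions. Independent lists of these sizes would share 94.1 and 37.6 genes. Unchanged groups simulated against the same Hoxa9-Meis1 arrays shared 0 in 50 draws, which is no measure of the overlap that shared arrays add, since the test is built to call almost no gene without an effect. The shared genes were 59.1% of the floxed calls and 33.9% of the deleted calls. The log2 differences of the 2 comparisons correlated at 0.62 across genes, which are not independent, against 0.50 for simulated unchanged groups. Their covariance was 0.224 against 0.0282, an excess of 0.196. The 3 Hoxa9-Meis1 arrays cannot be split into sets of at least 2, so part of the overlap beyond that of independent lists may come from the shared arrays. The shared count was 420 without Hoxa9-Meis1 replicate 1 and 491 without replicate 2.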

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

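The tests of the Hoxa9 and Meis1 probe sets, of array-wide trends among chromosomes and of the immediate early genes were chosen only after the result was seen. The random gene sets, the parts of chromosomes and the other splits of the arrays were not. The chromosomes put to these tests, however, were picked because they stood highest on their arrays.

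Probe sets without a single named gene also differed between deleted and floxed leukemias. Of 10092 such probe sets, which no comparison above used, 556 passed (limma adjusted p under 0.05 over all probe sets), 159 higher and 397 lower in deleted leukemias, or 5.51% against 6.38% of the named probe sets. Which transcripts they measure was not examined.

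Of the 10 splits of the 6 arrays of a comparison into 3 and 3, 1 gave as many called genes as the real one, namely the real one itself, and this held in each comparison. The real counts were 1246, 1618 and 2821, and the highest of the other splits 0, 0 and 1. A total of 10 splits is too few for a share under 0.05. The other splits also mix arrays of the 2 groups, so a difference between the groups widens their spread and lowers their counts.

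The Hoxa9 probe sets parted in Hoxa9-Meis1 leukemias. The gap between them was at least 8.48 (log2) wider on every Hoxa9-Meis1 array than on any MLL-AF9 array, while their changes between deleted and floxed leukemias differed by 0.0795, which argues against 1 of them failing to measure Hoxa9. A candidate explanation is that 1 probe set reads the vector's transcript, which lacks the part the other reads, and that the endogenous gene is low, since the 8 other measured HoxA genes lay at a median of -2.46 against floxed leukemias. For Meis1 every probe set was lower in Hoxa9-Meis1 leukemias, the highest difference being -3.22. Probe sets that miss the vector's transcript, and a low level of that transcript, cannot be told apart because no Meis1 probe set was higher there and probe sequences were not used here.

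In 3 arrays a single chromosome stood apart from the others. Chromosome 1 was higher by a median of 0.319 in deleted replicate 6 (1.25-fold, 527 genes of the brighter part, 79.5% of them above the array's centre), chromosome 15 by 0.256 in floxed replicate 4 (1.19-fold, 348 genes) and chromosome 5 by 0.152 in floxed replicate 6 (1.11-fold, 598 genes). The highest of 10000 random gene sets of these sizes reached 0.0575, 0.0657 and 0.0394, which argues against chance for a chromosome fixed beforehand. Each chromosome was picked as the highest of its array, and the random sets do not allow for that choice. The next chromosome of the first 2 arrays stood 0.081 and 0.0621 from the centre, against an array-wide trend. On floxed replicate 6 the next was chromosome 15 at 0.0764, past the bound set for a trend, so a trend cannot be told apart there. The lowest of 4 parts of each chromosome in gene order was at 0.239, 0.161 and 0.108, consistent with the hypothesis that part or all of these cells carried an extra copy, which no DNA measurement here tests, and other biological explanations were not tested. Floxed replicate 5, where chromosome medians ran from -0.166 (chromosome 7) to 0.204 (chromosome 13) and no single chromosome stood apart, was not put to these tests.

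Immediate early genes were lower in floxed than in Hoxa9-Meis1 leukemias, a call not made with an estimated correlation (adjusted p = 0.189). The list stayed past its test without each Hoxa9-Meis1 array in turn (highest camera adjusted p = 5.75e-10), which argues against a single array as the cause. Different handling of sorted and unsorted cells may contribute, since deleted leukemias, also sorted, had a list median of -1.01 against the same arrays. Handling cannot be told apart from oncogene, vector or transplant generation, because both sorted groups are MLL-AF9 leukemias from secondary recipients. These biological differences stay open as untested.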

How the results depend on the processing

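Without deleted replicate 6 and floxed replicate 5, without chromosomes 1, 5 and 15, and with a pseudocount of 32 were alternatives chosen after seeing the data. For deleted versus floxed, the 1246 genes became 2277 probe sets with every probe set tested, 711 with a log2 change of at least 1, 599 with the replicate block, 498 without deleted replicate 6 and floxed replicate 5, and 645 to 1204 with 1 array left out, lowest without floxed replicate 5. The labels do not say whether the replicate numbers pair the samples. Deviations of same-numbered arrays correlated at 0.033, 0.053 and 0.0086, and not every array correlated best with its own number, so the numbers were not used as pairs. With the block, the calls of Hoxa11 (limma adjusted p = 0.0598), Aff3 (0.06), Cxcr2 (0.0594) and Cd79b (0.0502) ended, among others. The late neutrophil list then had a camera adjusted p of 0.0645. The 6 lists became 2 with an estimated correlation and 3 without the chromosomes, where fewer genes were tested. The 4 Mllt10 probe sets became 2 with the replicate block and 2 to 4 with 1 array left out, lowest without deleted replicate 4 or 5 or floxed replicate 4 or 6. For floxed versus Hoxa9-Meis1, the 1618 genes became 3202 probe sets, 2543 with array weights, 721 with a log2 change of at least 1, and 681 to 1799 with 1 array left out, lowest without Hoxa9-Meis1 replicate 1. Its 8 lists became 0 with an estimated correlation and 5 without the chromosomes. For deleted versus Hoxa9-Meis1, the 2821 genes became 5328 probe sets, 1285 with a log2 change of at least 1, and 1540 to 2710 with 1 array left out, lowest without Hoxa9-Meis1 replicate 1. Its 4 lists became 0 with an estimated correlation, 2 without the chromosomes and 3 to 7 with 1 array left out, highest without deleted replicate 4. The 957 shared genes became 400 with a log2 change of at least 1 and 420 to 1157 with 1 array left out. The mean of a gene's probe sets reversed Hoxa9, to 3.30 for floxed (limma adjusted p = 0.0128) and 0.25 for deleted (limma adjusted p = 0.847) versus Hoxa9-Meis1, since its probe sets go opposite ways there. More probe sets than genes were tested with every probe set, and a stricter threshold lowers a count by construction; for the other shifts, among them those with arrays left out, the cause was not tested. The other counts stayed within 1.5 times of the main ones. Of the named genes called, 40 of 64, 42 of 63 and 63 of 72 in the 3 comparisons kept their call in every setting in which they were tested. The threshold of 1 on the log2 change was not applied to single named genes. A gene that a setting left out, as dim or by its chromosome, was not judged in that setting. Signal over background limits the dim genes, for which a change is understated.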

Other observations

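The test of gene families, and the choice of the genes named here, came after the data were seen; the test of neighbouring genes was fixed before its result was seen, except for its repeat without chromosomes 1, 5 and 15.

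Some neighbouring genes moved together after Af10 deletion. The immunoproteasome gene Psmb8 was at 11.23 ± 0.07 in deleted and 12.88 ± 0.19 in floxed leukemias (difference -1.65, SE 0.13, limma adjusted p = 0.000164), its neighbour Psmb9 differed by -0.91 (limma adjusted p = 0.00102) and the peptide transporter gene Tap1 by -1.02 (limma adjusted p = 0.00575), while Tap2 did not pass (-0.17, limma adjusted p = 0.85). In Hoxa9-Meis1 leukemias Psmb8 was at 12.71 ± 0.13. Of the receptor genes for the constant part of IgG, 3 neighbours were higher: Fcgr4 by 1.93 (limma adjusted p = 0.00398), Fcgr3 by 0.88 (limma adjusted p = 0.0166) and Fcgr2b by 0.62 (limma adjusted p = 0.0441), while Fcgr1 did not pass (0.42, limma adjusted p = 0.213). None of this was tested for a group of genes. A shift of a whole chromosome on 1 array, as seen for chromosome 1 in deleted replicate 6 (0.319), would also move neighbours together. The chromosome 1 shift favours rises of its genes in deleted leukemias, the direction of the 3 Fcgr neighbours. Neither the Fcgr genes nor the Psmb and Tap genes were tested apart from such shifts. Apart from Fcgr1 and Fcgr3, members of the monocyte list, these genes belonged to no fixed list, and the probes of related Fcgr genes can cross-hybridise.

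Among 425 families of at least 6 genes that share a symbol stem, 3 were past camera's test for deleted versus floxed leukemias. Besides the Hoxa genes, these were the Armcx genes of the X chromosome, of which 3 of 6 fell (median -0.83, adjusted p = 0.0204), and the Igkv genes, variable segments of the immunoglobulin light chain with similar sequences, of which 3 of 13 rose (median 0.65, adjusted p = 0.0261). Armcx4 differed by -2.51 (SE 0.18, limma adjusted p = 0.000121). Several families were past the test against Hoxa9-Meis1 leukemias. Among them, mitochondrial ribosomal protein genes (Mrpl) were higher in both MLL-AF9 groups, which were compared with the same Hoxa9-Meis1 arrays. Of 47, 5 were called in floxed (camera adjusted p = 0.000713) and 13 in deleted leukemias (camera adjusted p = 0.00113). Of all genes, 8.89% and 15.5% were called in these comparisons. None of these families was past the test with an estimated correlation (adjusted p of 0.927 to 0.998).

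Genes that fell after Af10 deletion lay next to each other more often than under shuffled gene order, with 75 neighbouring pairs in which both fell against a mean of 23.7 and a highest value of 37 in 1000 shuffles. The longest runs were Hoxa4 to Hoxa11 (6 measured genes) and Smim14, Ube2k, Pds5a, N4bp2 and Rhoh (5 genes). Genes that rose formed 51 such pairs, against a mean of 18.6 and a highest value of 32. Without chromosomes 1, 5 and 15, the counts were 56 and 40, against highest values of 34 and 29. Regulation of neighbouring genes together is a candidate explanation, and shifts of whole chromosomes on single arrays are another. The repeat cannot exclude such shifts, since on floxed replicate 5 other chromosomes also departed from the centre, from -0.166 to 0.204. The runs named were counted with all chromosomes, so a run on chromosome 1, 5 or 15 is not part of the repeat. Chromosomes 5 and 15 were raised on floxed arrays, which favours falls of their genes after deletion. Chromosome 1 was raised on a deleted array, which favours rises. Overlapping transcripts and probes that bind related neighbours were not tested.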
